A study of Arabidopsis thaliana with 6 samples.

How the data were processed

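Root RNA of 6 samples was labelled with biotin and hybridised to 1-colour Affymetrix ATH1 arrays, per the labels. The deposited values are signal intensities on a linear scale, made by the authors with MAS5, per the submitters' processing notes, which give no version or scaling setting. MAS5 subtracts background, combines the probes of a set into a robust average and scales each array by a single factor. The deposited columns themselves show the scaling, since after removing 2% of the values at each end every column had a mean of 100.01. Detection calls were not used here, so no probe set is called absent. A single factor per array does not align the dim end of the distributions, and signals under 16 made up 25.4% to 29.8% of the probe sets under nitrate minus and 32.4% to 33.4% under continuous nitrate.

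Columns were assigned to samples and groups from the sample titles. No pair of arrays shared a value in any probe set, so all 6 were counted as separate samples. The table gives probe set identifiers with no gene names, and the reference table used here pairs gene loci with symbols and not with probe sets. The 23 gene lists fixed before the data were examined were therefore not tested, and the knock-out was not checked in the arrays. The 64 Affymetrix control probe sets were left out of the tests and described separately.

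Values were taken as log2(signal + 16). Probe sets with a mean signal over all 6 arrays at or above the 40th percentile, a signal of 28.2, were tested, which left 13648, among them 489 of type s_at and 19 of type x_at, whose probes can match several transcripts. Tests used limma 3.58.1 in R 4.3.3 with an intensity trend in the variance prior, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The averaged nitrate and genotype comparisons came from an additive model of genotype and nitrate over 6 arrays, with 3 residual degrees of freedom. The comparisons within a genotype or nitrate condition and the interaction came from a model of 4 group means, with 2 residual degrees of freedom, all from the replicated nitrate-minus groups. Mutant against wild type under continuous nitrate, 1 array each, was described without a test.

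The rule for named probe sets took, among calls whose arrays did not overlap between the compared groups, those with the largest log2 fold change in each direction. It was written for genes, and since no gene names were paired with the probe sets it was applied to probe sets and limited to 2 per direction in the averaged comparisons and in mutant against wild type under nitrate minus. The model code was tested on simulated data with 200 changed probe sets among 13648. Of changes of 1 on the log2 scale it recovered 98% in the averaged nitrate comparison, 100% in the averaged genotype comparison and 93% in mutant against wild type under nitrate minus. It recovered 100% of changes of 2 in each, and called 8, 6 and 5 unchanged probe sets. The simulated noise was independent between arrays and drawn from the fitted variance prior, with no shift between arrays. These figures therefore check the code and do not measure how reliable the calls in the real arrays are.

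The design, the named-gene rule and the alternatives were set before the data were examined. The alternatives were quantile normalization, median centring, constants of 1 and 64 before the logarithm, no dim filter and a 60th percentile filter, no variance trend, the replicate number as a block, the average of the 4-group contrasts, the nitrate-minus arrays alone, and leaving out each array. A fit of the arrays numbered 1 alone was added after seeing the data. The groups under nitrate minus shared replicate numbers 1 and 2, and the labels do not say that a number marks a shared culture or day, so the main fits carried no block.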

Results

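Transcript levels were measured in whole root systems of Arabidopsis thaliana with 6 Affymetrix ATH1 arrays, each carrying 22810 probe sets, a probe set being the group of short oligonucleotides that reports on a transcript or a few related transcripts. Plants of the Col-0 accession (wild type) and a knock-out mutant labelled ANR1 in the same background were grown in hydroponics at 20 °C with 8 h light and 16 h dark. ANR1 is a MADS-box transcription factor gene known for its part in the lateral root response to nitrate. Roots came from plants whose nitrate supply was labelled minus or continuous. Under nitrate minus there were 2 arrays of wild type and 2 of the mutant, and under continuous nitrate 1 array of each genotype. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

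The deposited table pairs no probe set with a gene name, so ANR1 itself was not checked here and probe sets are given by their identifiers. The exceptions are Affymetrix control probe sets, whose identifiers name the transcript. Signals of all 6 arrays shared a trimmed mean of 100.01, and their medians lay between 39.8 and 46.0. Replicate arrays differed by an SD of 0.22 on the log2 scale in wild type and 0.20 in the mutant over 13648 probe sets bright enough to be tested. Single mutant and wild type arrays under nitrate minus differed by an SD of 0.24 to 0.27, and the 2 continuous arrays by 0.23. Arrays of the same genotype from different nitrate supplies differed by an SD of 0.46 to 0.51.

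The first comparison asked which root transcripts respond to nitrate supply, averaged over both genotypes. Of 13648 probe sets, 3268 rose and 2492 fell under nitrate minus, together 42.2% of those tested. Most changes were small, with a median size of 0.49 on the log2 scale among the called probe sets, and 246 rises and 190 falls reached 2-fold. The largest rise was that of 261198_at, from signals of 11.4 in wild type and 6.47 in the mutant under continuous nitrate to 1000 ± 46.1 (SD, n = 4) under nitrate minus. Its log2 fold change was 5.36 ± 0.09 (SE; adjusted p = 1.39e-10, limma). Probe set 247591_at rose from 3.38 and 5.43 to 289 ± 50.1 (SD, n = 4), a log2 fold change of 3.89 ± 0.13 (SE). The largest fall was that of 262399_at, from 887 in wild type and 899 in the mutant to 55.3 ± 9.98 (SD, n = 4), a log2 fold change of -3.68 ± 0.11 (SE; adjusted p = 1.2e-08, limma). Probe set 251072_at fell from 291 and 257 to 12.4 ± 7.28 (SD, n = 4), a log2 fold change of -3.39 ± 0.15 (SE). These fold changes are on the log2(signal + 16) scale, which understates changes that start or end at a dim signal. With a constant of 1 or 64 in place of 16 the log2 fold change was 6.70 or 3.87 for 261198_at and 5.76 or 2.36 for 247591_at, so the size of these rises is set largely by the constant. With a constant of 1, 251072_at fell more than 262399_at, the log2 fold changes being -4.59 and -4.01.

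Among Affymetrix control transcripts, the middle actin probe set, which reports a cytoskeletal gene often used as a reference, read 861 ± 29.4 (SD, n = 4) under nitrate minus and 1068 ± 105 (SD, n = 2) under continuous nitrate. The middle ubiquitin probe set read 905 ± 56.2 (SD, n = 4) under minus and 1188 ± 246 (SD, n = 2) under continuous nitrate. The middle probe set of GAPDH, a glycolytic enzyme, read 1859 ± 191 (SD, n = 4) and 1883 ± 235 (SD, n = 2). Over all their control probe sets, the ratio of the continuous to the minus mean was 0.825 to 1.46 for actin (6 probe sets, 5 higher under continuous nitrate), 1.01 to 1.495 for GAPDH (5 probe sets, all higher) and 1.02 to 1.37 for ubiquitin (5 probe sets, all higher). The ratio of 3' to 5' signal rises as RNA degrades. In the pair of probe sets first taken for each transcript it had a higher mean under continuous nitrate. For GAPDH it was 0.717 ± 0.090 (SD, n = 4) under minus and 0.888 ± 0.042 (SD, n = 2) under continuous nitrate, for ubiquitin 1.78 ± 0.12 and 2.1 ± 0.02, and for actin 1.17 ± 0.14 and 1.41 ± 0.06. Over all 6 pairs on the array, 4 were higher and 2 lower under continuous nitrate, the lower ones being the second pairs of GAPDH, 1.15 ± 0.09 and 1.04 ± 0.04, and of ubiquitin, 1.33 ± 0.14 and 1.18 ± 0.11. The second pair of actin had the highest ratios, 5.23 ± 0.84 (SD, n = 4) under minus and 6.99 ± 0.58 (SD, n = 2) under continuous nitrate. An exact two-sided permutation test of 2 arrays against 4 cannot go below p = 0.0667, and it gave that value for the middle actin and ubiquitin probe sets and for the first GAPDH and ubiquitin ratios, 0.133 for the first actin ratio and 1 for the middle GAPDH probe set. None of 20 such tests of array measures passed Benjamini-Hochberg adjustment, the lowest adjusted value being 0.167.

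Calls were made with limma at a Benjamini-Hochberg adjusted p of 0.05, and all 5760 had the same direction in both genotypes. Opposite effects would largely cancel in the averaged comparison, so this match was nearly fixed by the selection of calls. Without the wild type continuous array the comparison rests on the mutant alone and the count was 3004, and without the mutant continuous array it rests on wild type alone and was 3986. Hybridisation spike-ins of bacterial and phage origin split the arrays by replicate number in their geometric mean signal. It was 88.1 ± 0.41 (SD, n = 2) in the arrays numbered 2 and 134 ± 19.5 (SD, n = 4) in those numbered 1, which include both continuous arrays (exact permutation p = 0.0667). By nitrate supply it was 135 ± 11.4 (SD, n = 2) under continuous nitrate and 111 ± 31.8 (SD, n = 4) under minus (exact permutation p = 0.4). Some single spike-in probe sets separated by nitrate supply, in either direction. AFFX-BioDn-5_at read 166 and 132 in the wild type and mutant continuous arrays and 27.9 to 76.6 under minus. AFFX-r2-Ec-bioB-M_at read 32.9 and 30.6 there and 38.4 to 71.0 under minus. Within the arrays numbered 1 alone, in a fit with 1 residual degree of freedom, 4482 probe sets were called, 2477 higher and 2005 lower. Of these, 4238 were also called over all 6 arrays in the same direction. The arrays numbered 2 were all from nitrate minus and gave no value of their own.

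Taken separately, the genotypes gave nitrate responses that largely coincided. In wild type 2267 probe sets rose and 1703 fell under nitrate minus, and in the mutant 1699 rose and 1279 fell. Of the wild type rises, 2190 (96.6%) had a higher signal in the mutant as well, and of the wild type falls 1609 (94.5%) had a lower one. Both genotypes called 1214 rises and 892 falls, where independent lists of these lengths would share 282 and 160. The 2 contrasts have no array in common, but both took the variance of each probe set from the same nitrate-minus arrays. A probe set with a small spread there is called more readily in both, so part of the excess is built in. Across probe sets, which are not independent replicates, the nitrate effects of wild type and mutant had a Pearson r of 0.81 and a Spearman rho of 0.78. Effects of at least 2-fold were seen for 625 probe sets in wild type and 456 in the mutant, of which 288 were shared with the same sign and 3 with opposite signs. Each contrast set 2 arrays against a lone array, which was assumed to vary like the replicated groups, and without mutant minus replicate 1 the mutant count was 1922. Without the dim filter the mutant count was 1386 (794 rises, 592 falls) and that of wild type 3580.

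**Figure D1:**
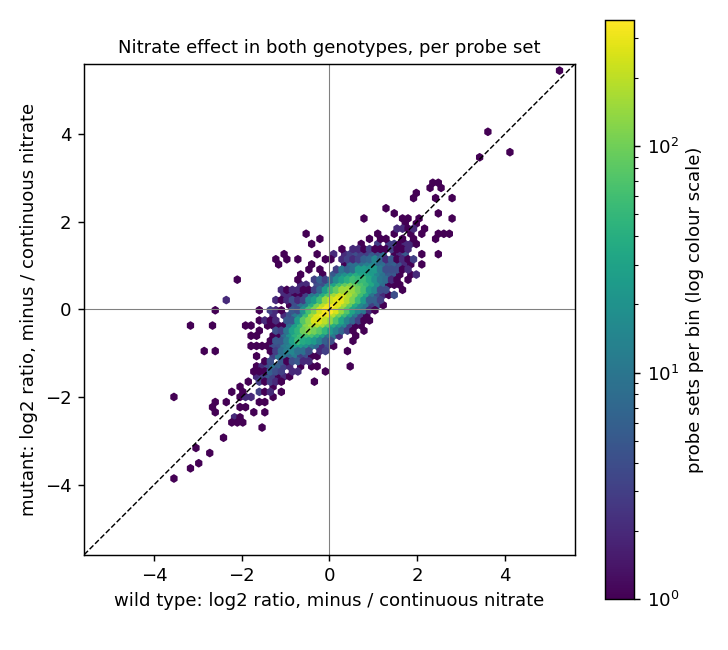
Log2 ratio of nitrate minus to continuous nitrate in wild type (x axis) and in the mutant (y axis) for 13648 probe sets, with colour giving the number of probe sets per bin on a log scale and the dashed line marking equal effects. Probe sets lie along the dashed line, with r = 0.81.

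The comparison of mutant and wild type under nitrate minus, the condition with replicates of both genotypes, asked which root transcripts differ when ANR1 is disrupted. Here 46 probe sets were higher and 33 lower in the mutant, and 22 rises and 7 falls reached 2-fold. The largest rise was that of 250464_at, from 20.6 ± 6.47 (SD, n = 2) in wild type to 175 ± 26.7 (SD, n = 2) in the mutant. Its log2 fold change was 2.39 ± 0.16 (SE; adjusted p = 0.000228, limma). Probe set 255807_at rose from 63.6 ± 8.94 to 330 ± 38.1 (SD, n = 2 each), a log2 fold change of 2.12 ± 0.13 (SE). With a constant of 64 in place of 16 it rose more than 250464_at, the log2 fold changes being 1.624 and 1.497. The largest fall was that of 251755_at, from 253 ± 46.5 to 80.9 ± 14.4 (SD, n = 2 each), a log2 fold change of -1.47 ± 0.15 (SE; adjusted p = 0.00313, limma). Probe set 267573_at fell from 217 ± 3.1 to 80.8 ± 5.07 (SD, n = 2 each), a log2 fold change of -1.27 ± 0.11 (SE). Without the dim filter 251755_at lost its call (adjusted p = 0.163, limma), and the other 3 named probe sets kept theirs.

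Of the 46 mutant rises, 9 were probe sets that fell under nitrate minus in the averaged nitrate comparison and 5 were probe sets that rose. Of the 33 mutant falls, 12 were probe sets that rose under nitrate minus and 11 were probe sets that fell. Among all 13648 tested probe sets 2492 fell and 3268 rose in that comparison. It shares the 4 nitrate-minus arrays with the genotype comparison, so these overlaps are not independent of the genotype calls. In mutant against wild type under nitrate minus, an unadjusted p under 0.05 was reached by 1894 probe sets, where chance alone would give 682. Without the filter on dim probe sets the count was 13, without wild type minus replicate 1 it was 312 (168 higher, 144 lower) and without wild type minus replicate 2 it was 510 (214 higher, 296 lower), the last 2 with a single residual degree of freedom.

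Under continuous nitrate each genotype had 1 array, so the difference has no replicate check and was not tested. On the log2(signal + 16) scale 43 of 13648 probe sets were at least 2-fold apart, 42 of them lower in the mutant and 1 higher. In 20 of the 42 the wild type continuous array lay at least 2-fold above each of the other 5 arrays, and in none of the 13648 did the mutant continuous array do so. For comparison, single mutant and wild type arrays under nitrate minus were at least 2-fold apart for 41 to 55 probe sets, and replicate arrays for 17 in wild type and 12 in the mutant. Of the 46 rises under nitrate minus, 24 were also higher in the mutant under continuous nitrate (52.2%), with a median log2 difference of 0.97 under minus and 0.02 under continuous nitrate. Of the 33 falls, 20 were also lower (60.6%), with medians of -0.79 and -0.16. None of the rises and 7 of the falls were at least 2-fold apart in the same direction under continuous nitrate. Rises and falls did not differ in how often they kept their direction (Fisher's exact test, two-sided p = 0.498, n = 79 probe sets, which are not independent). Over all tested probe sets the genotype differences of the 2 conditions had a Pearson r of 0.12 and a Spearman rho of 0.13. The count of 43 depended on the constant added before the logarithm, being 101 with 1 (28 higher and 73 lower in the mutant) and 15 with 64 (all lower).

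**Figure D2:**
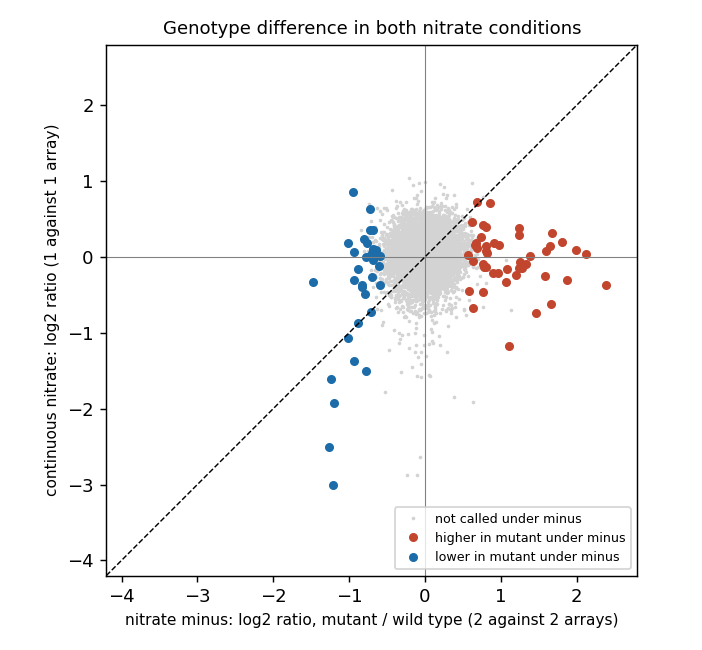
Log2 ratio of mutant to wild type under nitrate minus (x axis, 2 against 2 arrays) and under continuous nitrate (y axis, 1 against 1 array) for 13648 probe sets, with the 46 probe sets called higher and the 33 called lower in the mutant under nitrate minus in colour and the dashed line marking equal differences. The 46 rises centre on a continuous difference near 0 (median 0.02), while 7 of the falls lie at least 2-fold down under continuous nitrate.

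Averaged over both nitrate conditions, 4 probe sets were higher and 9 lower in the mutant. The 4 rises and 8 of the 9 falls were also called under nitrate minus alone. The minus arrays are part of the averaged comparison and weigh more in it than the continuous arrays, so this overlap was largely fixed beforehand. The falls included 267573_at, which read 210 in wild type and 24.0 in the mutant under continuous nitrate and whose averaged log2 fold change was -1.68 ± 0.20 (SE; adjusted p = 0.012, limma). Probe set 260624_at read 320 ± 0.18 and 130 ± 3.12 (SD, n = 2 each) in wild type and mutant under minus and 106 and 16.1 under continuous nitrate, an averaged log2 fold change of -1.44 ± 0.14 (SE). Of the rises, 256994_s_at read 139 ± 4.06 and 264 ± 27.8 (SD, n = 2 each) under minus and 109 and 190 under continuous nitrate, with an averaged log2 fold change of 0.81 ± 0.09 (SE), and its s_at ending marks probes shared by several transcripts. It lost its call in 4 of 16 alternatives, among them leaving out wild type minus replicate 1 (adjusted p = 0.0662, limma), wild type minus replicate 2 (0.0605) or mutant minus replicate 1 (0.0618). Probe set 264157_at rose by 0.70 ± 0.09 (SE) on the log2 scale, and lost its call in 6 of 16 alternatives, among them leaving out any 1 minus array (adjusted p 0.0781 to 0.115, limma). Without the dim filter limma called 0 probe sets at an adjusted p of 0.05, with 2151 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0637. Leaving out single minus arrays gave 5 to 7 calls, and leaving out either continuous array gave 79, since the comparison then rests on the minus arrays alone. The average of the 4-group contrasts gave 57 calls, 23 higher and 34 lower.

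The interaction asked whether the genotype difference depended on nitrate supply. In 31 probe sets the ratio of mutant to wild type was higher under nitrate minus than under continuous nitrate, and in 1 it was lower. The rises 250464_at and 255807_at were among the former, with differences between the conditions of 2.76 (adjusted p = 0.00469, limma) and 2.09 (adjusted p = 0.00581, limma) on the log2 scale. The fall 267573_at was also among them, its difference being larger under continuous nitrate. It was among the calls lost after quantile normalization, its interaction being 1.23 before and 1.07 after on the log2 scale. The single probe set in the other direction, 254326_at, was named after its values were seen. It read 156 ± 11.3 and 73.6 ± 7.31 (SD, n = 2 each) in wild type and mutant under minus, and 104 and 200 under continuous nitrate, an interaction of -1.79 ± 0.20 (SE; adjusted p = 0.00859, limma). Of the 46 mutant rises under minus, 18 were called for the interaction, and of the 33 falls 3 were. The test rests on 2 lone continuous arrays, which were assumed to vary like the replicated groups. Without the dim filter limma called 0 probe sets, with 1845 at an unadjusted p under 0.05, and without wild type minus replicate 1 or 2 it called 164 (107 higher, 57 lower) or 179 (107 higher, 72 lower). Without mutant minus replicate 1 or 2 the split was 34 to 4 or 35 to 4.

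**Figure D3:**
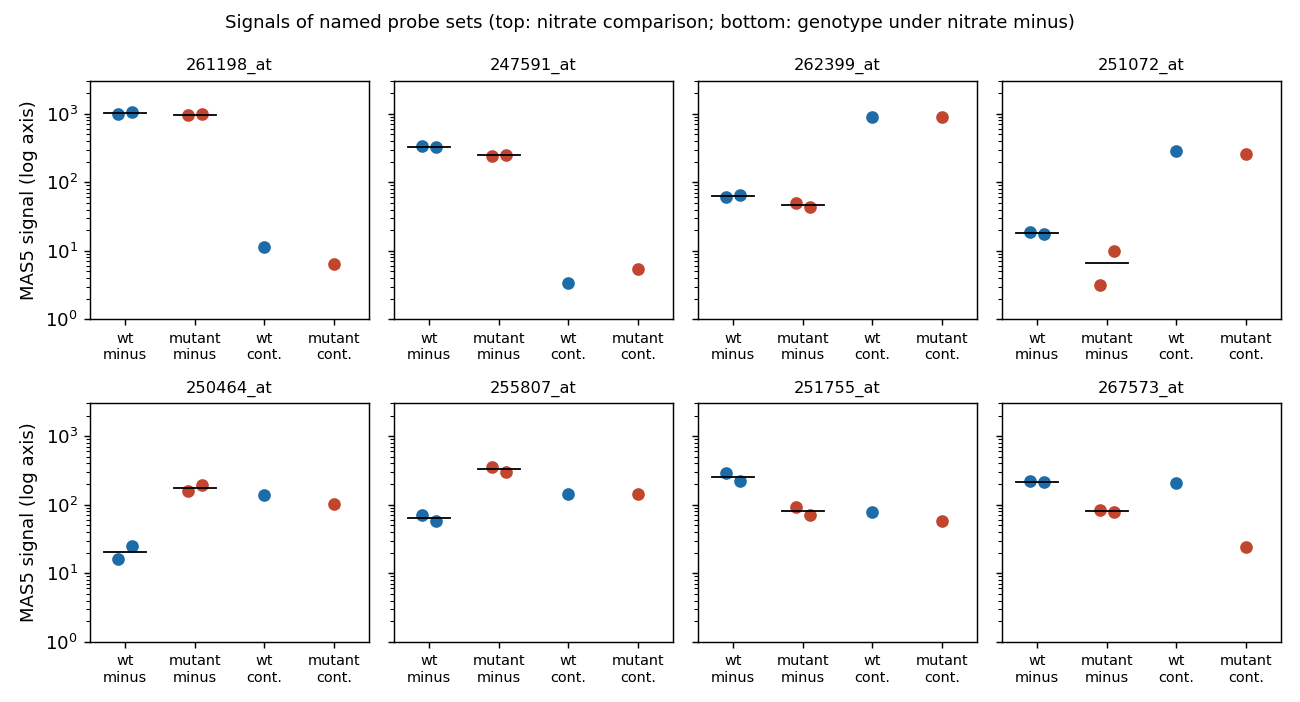
MAS5 signal (log axis) of 8 probe sets in each of the 6 arrays, blue for wild type (wt) and red for the mutant, with bars at the mean of the 2 arrays under nitrate minus and cont. for continuous nitrate. The top panels show 261198_at, 247591_at, 262399_at and 251072_at, which separate by nitrate supply, and the lower panels 250464_at, 255807_at, 251755_at and 267573_at, which separate by genotype under nitrate minus.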

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

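The test on the single continuous arrays was chosen after the interaction calls were seen, and the bound for the calls kept after quantile normalization was set after their number was seen.

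The genotype difference varied with nitrate supply in 31 probe sets whose mutant to wild type ratio was higher under nitrate minus, and in 1 whose ratio was lower, by the interaction term in limma. The split was 107 to 57 without wild type minus replicate 1 and 107 to 72 without replicate 2, and 34 to 4 and 35 to 4 without mutant minus replicates 1 and 2. In 17 of the 32 the genotype difference was larger under nitrate minus, where both genotypes had 2 arrays, and in 15 (46.88%) it was larger between the 2 single continuous arrays, with the mutant lower there in all 15. In 10 of the 32, the wild type continuous array lay at least 2-fold above each of the other 5 arrays. This was so for 20 of all 13648 probe sets, and for none did the mutant continuous array stand above the others in this way. A departure of that 1 array, whether of its plants or its hybridisation, cannot be told apart from an effect of genotype under continuous nitrate for these probe sets, because neither continuous group has a second array. After quantile normalization 21 of the 32 stayed called (65.62%). The 11 others had a median size of 1.36 with a median SE of 0.20 before it and 1.35 with 0.20 after it, and adjusted p of 0.0312 to 0.0428 before and 0.0529 to 0.109 after (limma), so they ended as calls near the threshold with little change in size. Median centring kept all 32, and the 60th percentile filter gave 26 calls, all among the 32. Whether the authors' scaling contributed to the 11 is not settled. An effect of ANR1 that depends on nitrate supply stays open.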

How the results depend on the processing

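Direction was kept by all 13 named results under every alternative run, 186 of 200 values stayed past the threshold and 14 did not, 6 of these without the dim filter. The named results were picked for large changes among the calls of these same arrays, so a kept direction was nearly fixed by that choice. The averaged nitrate count stayed within 1.5 times of 5760 under every setting except one left-out array, and its share of rises was lowest with the 60th percentile filter, 50.02%, and highest with no filter, 63.35%. Without the dim filter, which lowered the prior degrees of freedom from 7.055 to 3.24 in the 4-group model, the counts were 0 for the averaged genotype comparison (lowest adjusted p 0.06366), 13 for mutant against wild type under nitrate minus, 1386 for nitrate in the mutant and 0 for the interaction (lowest adjusted p 0.1688). All 13 calls of the genotype comparison under minus were among the 79. The average of the 4-group contrasts gave 57 calls for the averaged genotype comparison. The 2-fold count under continuous nitrate was 101 with a constant of 1, 15 with a constant of 64, 71 without the filter and 24 with the 60th percentile filter. With the replicate block the counts were 481 for mutant against wild type under minus (246 higher, 235 lower) and 129 for the interaction (89 higher, 40 lower), including all 79 and all 32 original calls; this fit had 1 residual degree of freedom, and its prior degrees of freedom rose to 15.22. With 2 pairs, the replicate deviations of wild type and mutant had r = 0.18, which does not settle whether the numbers pair the samples; the block moved no other count by over 1.5 times. Leaving out each array in turn gave 3004 to 5384 calls for averaged nitrate (lowest without wild type continuous, the mutant alone), 5 to 79 for averaged genotype (highest without a continuous array, the minus arrays alone), 53 to 510 for genotype under minus, 3930 to 4383 for nitrate in wild type, 1922 to 4323 for nitrate in the mutant and 38 to 179 for the interaction. The high ends of the last 4 came without a wild type minus array, where 1 residual degree of freedom was left and the prior degrees of freedom rose to 32.74 (without replicate 1) or 32.19 (without replicate 2). Nitrate in a genotype and the interaction had no value without that genotype's continuous array. The gene lists were not run. Outliers within groups were not tested, since no group held 4 arrays.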

Other observations

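The tests on dim signals, the count within the arrays numbered 1, RNA integrity and the position of the continuous arrays were chosen after the result was seen.

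Probe sets whose signal responded to nitrate supply were spread over the whole range of brightness. In the dimmest 3rd of the tested probe sets 1697 of 4550 were called (37.3%), and in the brightest 3rd 2177 of 4549 (47.9%). Rises made up 72.3% of the calls in the dimmest 3rd, 56.5% in the middle and 44.8% in the brightest. The nitrate effect was also somewhat larger in wild type than in the mutant. Among the called probe sets its median size was 0.53 in wild type and 0.47 in the mutant on the log2 scale, and 3394 of 5760 (58.9%) had the larger effect in wild type. This difference rests on 1 continuous array per genotype and was not tested.

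The excess of rises over falls under nitrate minus, 3268 against 2492, may come from the scaling of dim signals. The continuous arrays held more signals under 16, and a single scaling factor per array leaves that difference in place. Above the 60th percentile of brightness rises were 50.02% of the calls, against 56.74% in the main analysis. Their share after quantile normalization, 52.26%, was first counted as a test too and then withdrawn, since that normalization itself pulls rises and falls toward balance. A larger share of dim transcripts induced by nitrate removal would also give these values and stays open.

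The breadth of the nitrate response could have come from a hybridisation batch, since the mean spike-in signal separated the replicate numbers. A batch that follows the number is argued against by the arrays numbered 1 alone, among which the number cannot differ. A batch of the 2 continuous arrays would coincide with nitrate supply, also within the arrays numbered 1, and cannot be told apart from it. The arrays numbered 1 alone gave 4482 nitrate calls, 77.81% of the count over 6 arrays, and 10 genotype calls in the same fit. In a separate fit of the nitrate-minus arrays, replicate number separated 42 probe sets and genotype 490. Each fit left 1 residual degree of freedom, with prior degrees of freedom of 15.7 and 15.6. In the arrays numbered 1 alone 100% of the calls over 6 arrays kept their sign, with a median ratio of fold changes of 0.9964, but both values were nearly fixed beforehand, since these 4 arrays are among the 6 and 5730 of the 5760 calls had all arrays apart in both genotypes. A test of RNA integrity compared the nitrate-minus replicates, asking whether the one with the higher 3' to 5' ratio was displaced toward the continuous arrays in proportion. The displacement was 0.1144 of that expected in wild type and -0.0322 in the mutant, and with all 6 pairs of probe sets, computed afterwards, 0.0504 and -0.00995. With the first pair of each transcript this decides nothing, because the replicates differed in mean log2 ratio by 0.05 ± 0.15 in wild type and 0.09 ± 0.14 in the mutant (SE over 3 transcripts), so neither had a clearly higher ratio. With all 6 pairs the replicates differed by 0.07 in wild type and 0.17 in the mutant, and the nitrate groups by 0.16. The spread of these differences over the pairs was not computed, so that version decides nothing either. A difference in RNA integrity stays open beside a response to nitrate.

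The averaged genotype comparison gave 13 calls for the real split of the arrays, and 1 of the 10 splits into 3 and 3, the real one, reached that number, the highest other giving 4. The split with 4 calls kept the minus arrays grouped by genotype and exchanged only the continuous arrays, so it was not free of the genotype difference. With 10 splits the share cannot fall under 0.05, so the splits cannot decide whether the 13 calls arose by chance.

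A hypothesis was that the mutant under nitrate minus kept transcripts nearer to their level under continuous nitrate. On a scale from 0 at wild type minus to 1 at mutant minus, the continuous mean of the 46 mutant rises had a median position of 0.5561, with 28 nearer to the mutant and 18 nearer to wild type. It lay between both genotypes for 32, beyond the mutant for 10 and beyond wild type for 4. The median is too close to the middle to decide, so the test neither favours nor excludes the hypothesis. For the 33 falls, which the test did not cover, the median position was 0.69, with 11 between the genotypes, 11 beyond the mutant and 11 beyond wild type. Both continuous arrays lay above both wild type minus arrays for 37 of the 46 rises (80.4%), against 32.6% of all tested probe sets. They lay below both for 18 of the 33 falls (54.5%), against 37.3%. The wild type minus arrays also entered the choice of these probe sets, which favours such shares, so these values do not decide either.

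Ribosomal RNA gave a further difference between replicates. The 25S rRNA control probe set read 289 in wild type minus replicate 1 and 17.56 in replicate 2, 85.5 and 28.6 in the mutant minus replicates 1 and 2, and 269 and 229 in the wild type and mutant continuous arrays. The arrays numbered 2 were lower than those numbered 1 (exact two-sided permutation p = 0.0667, the smallest that 15 splits allow).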
